A study of Mus musculus with 10 samples.

How the data were processed

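RNA from 10 mouse placentas was sequenced as single reads of a stranded mRNA library, and the labels name the library kit in different ways in different places. The deposited table holds raw read counts per gene, whole numbers whose totals differ between libraries. Per the submitters' processing notes, bcl2fastq 2.20, cutadapt 3.4, HISAT2 2.2.1 and HTSeq 2.0.2 were used with the mm10 build, named without role or order. The annotation release and the strand setting of the counting are not stated in the sources used here. Total counts were 20026019, 21256423, 22645557, 20016836 and 19782852 in control replicates 1 to 5, and 25692285, 19087985, 19865246, 19167690 and 19132129 in ICSI-F2 replicates 1 to 5.

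The table held 32285 genes, of which 7553 had no count. Gene identifiers were matched to GENCODE mouse release M 21, which held 32235 of them and gave the coordinates, and 27 symbols that the file held as dates were restored from their identifiers. The column names matched the labels, and 0 columns belonged to other samples. Libraries were checked for duplication: the closest pair had a chi-square of 11.69 per degree of freedom, so no library repeated another.

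Groups were taken from the labels, with 5 libraries each. Genes were filtered with edgeR's filterByExpr on group, which kept 15308 genes holding 99.9% of counts, and scaled by TMM. Gene tests used edgeR 4.0.16 (glmQLFit and glmQLFTest, no covariates, prior degrees of freedom 3.74) with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists, 36 in all, were tested by camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the lists with at least 3 measured members. The level of a list in a library was the mean log2 CPM of its measured members, compared by an exact two-sided permutation test over all 252 assignments, whose smallest possible p is 0.00794. Spread within groups was the root mean square distance of each library from its group mean, tested in the same way. Within code numbers 60 assignments were possible, with a smallest p of 0.0167. No paired analysis was possible because the replicate numbers do not pair a control with an ICSI-F2 placenta. Counting error weighs most on genes with few counts, such as those near 1 CPM. Its share of the spread of each named gene was not tested.

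The tests, the gene lists, the rule for named genes and most other settings were chosen before the data were examined. The rule takes up to 5 genes per direction with the smallest p where fewer pass, up to 2 members of each list with the smallest p where none passes, and 14 genes always named. The other settings chosen at that time were other normalizations and filters, DESeq2 1.42.0, limma voom with and without sample weights, leaving out each library, the code number, the name style, summing or blocking libraries that share a number and letter, the Y-linked list, the decidua list and 1 surrogate variable (sva 3.50.0) as covariates, thinning to the smallest library, camera with an estimated correlation, and the self-contained test fry. Settings chosen after seeing the data were the yolk sac list as a covariate, leaving out both ends of the yolk sac range, the code number and Y-linked list together for gene lists, permutation within libraries with and without Y-linked reads, and 2 other sample orders for fry.

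The gene test was tested on simulated data of the same size with 200 changed genes. At 1.25-fold, 1.5-fold, 2-fold and 4-fold changes, with 50 genes each, edgeR recovered 10%, 70%, 86% and 92% and made 7 false calls among 136. DESeq2 recovered 32%, 78%, 90% and 98% with 39 false calls. For lists, 1 of 20 simulated draws with no change had a list past the threshold, and raising the cell cycle list by 0.5 log2 gave 1 list past it. Genes were simulated independently of each other, and other splits of the real libraries had a median of 9 lists past the threshold, so the simulated rate does not hold for these data. The number of draws was raised to 20, and DESeq2 was run on all 100 splits, after smaller draws had given unequal counts. Computations used R 4.3.3 and Python 3.11.15, with numpy 2.4.6 and matplotlib 3.10.9 for figures.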

Results

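Gene expression was measured by RNA sequencing in 10 mouse placentas collected at E13.5, a stage of embryonic development in midgestation. They fall into 5 controls and 5 placentas of the group called ICSI-F2. ICSI is intracytoplasmic sperm injection, in which a single sperm is injected into an oocyte. Per the labels, ICSI-F2 conceptuses descend from C57BL/6 mice made in that way, through a male of that line mated naturally to a wild-type C57BL/6 female, and controls come from natural mating to a wild-type male. The comparison asks whether the placentas of such descendants differ in gene expression from those of controls. The labels disagree on whether the father is the F1 or the F2 male, so the generation is given here only as the group name. The 10 libraries held between 19087985 and 25692285 counts, and 15308 of 32285 genes passed the filter on low counts. Total counts averaged 20750000 ± 1210000 in controls and 20590000 ± 2870000 in ICSI-F2 (SD, n = 5 each, exact two-sided permutation p = 0.944). The labels do not say whether the placentas came from separate dams or litters, so each p-value measures only the spread between these samples. Some libraries share a code number and letter, and those that do always lay in the same group. The main tests treat all 10 libraries as independent, so their p-values may be too small if such libraries are related.

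Lists of uterine natural killer and T cell, trophoblast giant cell and heat shock genes lay higher in ICSI-F2 placentas than in controls, and paternally expressed imprinted genes lower, by the test camera with a preset correlation. None of these 4 lists passed with an estimated correlation (adjusted p = 0.336 for each) or by permutation of list levels (0.0952 adjusted for each), and the heat shock call ended with the Y-linked list as a covariate. No single gene passed the test over all genes. The smallest p-values belonged to 5 genes that were higher in all 5 ICSI-F2 placentas than in any control. Tfpi, an inhibitor of tissue factor that restrains blood coagulation, averaged 562 ± 37.5 CPM (counts scaled to the TMM-adjusted library total) in controls and 886 ± 110 in ICSI-F2 (SD, n = 5 each). Its log2 fold change was 0.66 ± 0.0842 (SE), with an adjusted p of 0.0721 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Klra7, a receptor of natural killer cells, differed by 2.63 ± 0.357 on the log2 scale, from 0.272 ± 0.118 to 1.71 ± 0.542 CPM (SD, n = 5 each). Klra7 belongs to a family of similar genes, so its reads are uncertain. The integrin gene Itga2 had a log2 fold change of 0.41 ± 0.0582, Sema7a, a membrane-anchored semaphorin, 0.33 ± 0.0485, and Adam8, a membrane protease, 0.61 ± 0.0942 (SE). The adjusted p was 0.0721 for Itga2 and Sema7a and 0.0874 for Adam8 by the same test.

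A further 5 genes had the smallest p-values among those lower in ICSI-F2, and each lay below every control in all 5 placentas. Ogn, which encodes the matrix proteoglycan osteoglycin, averaged 4.45 ± 4.86 CPM in controls and 0.444 ± 0.183 in ICSI-F2 (SD, n = 5 each), a log2 fold change of −3.30 ± 0.684 (SE). Nptxr, a receptor of neuronal pentraxins, had a log2 fold change of −0.58 ± 0.123, Tmem136 −0.38 ± 0.0739, Chd3, a chromatin remodeller, −0.33 ± 0.0706, and Rhot2, a mitochondrial GTPase, −0.25 ± 0.0526 (SE). All of these had an adjusted p of 0.168 by edgeR. On the GRCm38 (mm10) assembly, the gene Tfpi spans chromosome 2 from 84432855 to 84476775, Klra7 chromosome 6 from 130218605 to 130233322, and Ogn chromosome 13 from 49608046 to 49624501.

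Over all genes tested, 0 passed an adjusted p of 0.05 by edgeR, and 7 passed 0.10. At an unadjusted p under 0.05 there were 2049 genes, of which 1129 were higher and 920 lower in ICSI-F2, where 765 would be expected by chance. In 328 genes (2.14%) the groups did not overlap, against 0.794% expected by chance, with 220 higher and 108 lower. DESeq2's Wald test called 313 genes, 231 higher and 82 lower, and limma voom called 1, Tfpi. With the level of Y-linked genes as a covariate, 0 genes passed and 825 had an unadjusted p under 0.05. Without control replicate 1, 4 genes passed (Prl7a1, Ceacam9, Tfpi and Prl2c3), without ICSI-F2 replicate 1 only Tfpi, and without ICSI-F2 replicate 5 only Klra7. The libraries carry a code number, 37 or 63, that the labels do not explain and that is unequal between the groups. With it as a covariate 10 genes passed, 5 higher and 5 lower, and with the style of the library name as a covariate 31 passed, 21 higher and 10 lower. Among libraries of code number 63 alone 1 gene passed (Muc16, lower), and among those of code number 37 alone, with a single ICSI-F2 placenta assumed to vary like the controls, 4 passed (Kdm5d, Uty and Ddx3y lower, Xist higher). These 4 only restate that this placenta had no Y-linked reads while its 3 controls had them, so they are no evidence on ICSI-F2. Prl7a1, Muc16 and Ddx3y are named here after their values were seen.

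Genes of uterine natural killer and T cells, the cells that populate the maternal side of the rodent placenta, had the smallest p by camera. All 11 measured members were higher in ICSI-F2, with a mean log2 fold change of 1.28. Gzmb, a cytotoxic granule protease, averaged 10.4 ± 5.64 CPM in controls and 34.2 ± 10.6 in ICSI-F2 (SD, n = 5 each), a log2 fold change of 1.72 ± 0.359 (SE). Gzme, a granzyme typical of uterine natural killer cells, averaged 55.1 ± 29.2 CPM in controls and 153 ± 44.5 in ICSI-F2, and Ptprc, the pan-leukocyte antigen CD45, 9.47 ± 3.04 and 19.6 ± 5.15 (SD, n = 5 each). Their adjusted p over all genes was 0.168 by edgeR. With p adjusted over the list alone, 10 members passed, all higher. The list passed the competitive test camera with an adjusted p of 5.14e-11 over the 36 lists, but had an adjusted p = 0.336 with an estimated correlation. The mean level of the list per placenta was 4.72 ± 0.681 log2 CPM in controls and 6.09 ± 0.394 in ICSI-F2 (SD, n = 5 each, exact two-sided permutation p = 0.0159, 0.0952 after adjustment), and 4 of 5 ICSI-F2 placentas lay above all controls. Within the code numbers of the libraries the difference was 1.34 (exact permutation p = 0.0167, the smallest that this arrangement can give, 0.06 after adjustment). Within libraries with and without Y-linked reads, a setting chosen after seeing the data, it was 1.24 (exact permutation p = 0.04, the smallest that 25 assignments can give, 0.64 after adjustment). The 5 members Gzmc to Gzmg have close paralogous sequences, so their reads may be shared among them.

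**Figure D1:**
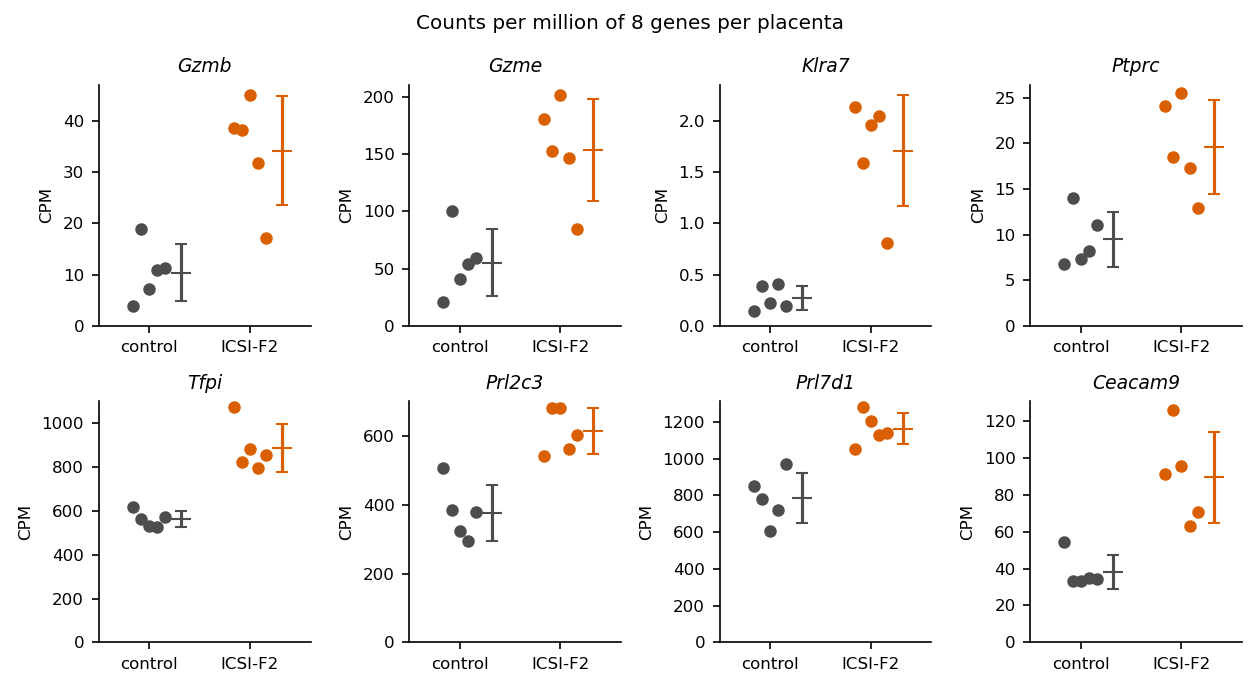
TMM-scaled CPM (y axis from 0) of 8 genes in 5 control (grey) and 5 ICSI-F2 (orange) placentas, with a point per placenta and the mean and SD as dash and bar. Gzmb averaged 10.4 CPM in controls and 34.2 CPM in ICSI-F2, and Tfpi 562 and 886 CPM.

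Other maternal and immune lists did not pass. The maternal decidua list had 13 of 19 members higher, with an adjusted p of 0.106 by camera, and a level difference of 0.15 (exact permutation p = 0.333). The median expression level of its members per placenta differed by 0.586 (exact permutation p = 0.0476, 0.19 adjusted), in the direction of the natural killer list. That value is not the change of a typical member, since the median of the members' log2 fold changes was 0.0843. Gzme belongs to both lists, and without Gzme the median level of the decidua list differed by 0.31. The adjusted p by camera became 0.0423 without control replicate 2 and 0.0443 without ICSI-F2 replicate 5. Its members with the smallest p were Gzme and the muscle intermediate filament gene Des, which averaged 469 ± 97.6 CPM in controls and 637 ± 85.4 in ICSI-F2 (SD, n = 5 each). The macrophage and granulocyte list had 10 of 13 members lower and did not pass (adjusted p = 0.0531 by camera). Within it S100a8, a granulocyte calcium-binding protein, was 16.5 ± 4.26 CPM in controls and 29.0 ± 4.07 in ICSI-F2, while Lyve1, a marker of tissue macrophages and lymphatics, was 11.7 ± 2.83 and 8.60 ± 1.2 (SD, n = 5 each). Of these, only S100a8 passed with p adjusted over the list alone.

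In trophoblast giant cells, the large polyploid cells at the maternal border, 11 of 14 measured genes were higher, 7 passed with p adjusted over the list alone (6 higher, 1 lower), and the list rose by camera (adjusted p = 0.000781; adjusted p = 0.336 with an estimated correlation). Prl2c3, a proliferin hormone gene, averaged 378 ± 81.6 CPM in controls and 615 ± 66.1 in ICSI-F2, and Prl2c5 798 ± 123 and 1075 ± 47.1 (SD, n = 5 each). Proliferin genes are near-identical copies, so reads may be divided between them uncertainly. The list level was 8.14 ± 0.105 log2 CPM in controls and 8.37 ± 0.10 in ICSI-F2 (SD, n = 5 each, exact permutation p = 0.0159, 0.0952 adjusted). Within libraries with and without Y-linked reads the difference of this level was 0.189 (exact permutation p = 0.08, 0.64 adjusted). The median expression level of the members per placenta differed by 0.024 (exact permutation p = 0.794), while the median of their log2 fold changes was 0.214.

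Of 21 prolactin family genes of the placenta, 14 were higher and 7 lower, and 10 passed with p adjusted over the list alone (8 higher, 2 lower). Prl7d1 averaged 784 ± 137 CPM in controls and 1161 ± 84.6 in ICSI-F2 (SD, n = 5 each). The list passed camera upwards (adjusted p = 0.00517), with adjusted p = 0.388 with an estimated correlation, and its level difference of 0.057 log2 was within the spread of the samples (exact permutation p = 0.595, n = 5 per group). The difference of the list prolactin family of the placenta turned to −0.013 without ICSI-F2 replicate 5 and to −0.012 without ICSI-F2 replicate 4, which ended the call (adjusted p = 0.0857 and 0.0526), as did the code number as a covariate (0.0672).

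Of 13 trophoblast progenitor genes, 8 were higher and 5 lower, with a median log2 fold change of 0.087 and 3 passing over the list alone, all higher, and every ICSI-F2 level lay above every control level. Their level was 6.33 ± 0.0836 log2 CPM in controls and 6.52 ± 0.0379 in ICSI-F2 (SD, n = 5 each, exact permutation p = 0.00794, the smallest that 252 assignments can give, 0.0952 adjusted). Eomes, a transcription factor of trophoblast stem cells that natural killer cells also use, averaged 4.55 ± 1.43 CPM in controls and 9.39 ± 2.36 in ICSI-F2, and Ly6a 95.9 ± 18.6 and 129 ± 15.6 (SD, n = 5 each). Within libraries with and without Y-linked reads the level difference was 0.154 (exact permutation p = 0.04, 0.64 adjusted). Within code numbers it was 0.166 (exact permutation p = 0.0167, 0.06 adjusted). The list passed camera (adjusted p = 0.026; adjusted p = 0.336 with an estimated correlation), and did not with the code number (0.112), with the Y-linked list (0.0758), or without control replicate 3 (0.0623) or ICSI-F2 replicate 5 (0.0918).

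Spongiotrophoblast and labyrinth lists passed camera downwards, but their levels did not differ beyond the spread of the samples (exact permutation p = 0.198 and 0.135, 0.351 and 0.302 adjusted). Of 27 spongiotrophoblast genes, 20 were lower, and the list passed camera (adjusted p = 0.00517; adjusted p = 0.641 with an estimated correlation). Only 2 members passed over the list alone, and these were higher: Ceacam9 went from 38.1 ± 9.23 to 89.4 ± 24.6 CPM and Psg22, a pregnancy-specific glycoprotein, from 114 ± 18.9 to 155 ± 13.2 CPM (SD, n = 5 each). Tpbpa, the classic marker of this layer, was 5702 ± 854 CPM in controls and 5765 ± 1310 in ICSI-F2. The mean difference of the list was −0.40 on the log2 scale and turned to 0.0028 with the Y-linked list as a covariate, and without ICSI-F2 replicate 3 it was −0.24 (adjusted p = 0.151). The call also ended with the code number (0.128), the decidua list (0.173) or the yolk sac list (0.0828) as a covariate. Of 17 syncytiotrophoblast genes of the labyrinth, the exchange layer, 15 were lower, and the list passed camera (adjusted p = 0.00413; adjusted p = 0.533 with an estimated correlation), with no member passing over the list alone. Its examples were Slc13a4, a sulfate transporter, at 171 ± 21.6 and 129 ± 28.5 CPM, and Gcm1, the transcription factor of labyrinth branching, at 22.2 ± 3.29 and 18.3 ± 2.56 CPM (SD, n = 5 each). Without control replicate 5 the adjusted p of the labyrinth list was 0.0572, and with counts summed per number and letter of the library code it was 0.0833. Glycogen trophoblast genes did not pass (8 of 12 higher, adjusted p = 0.0546), with Plac8 at 229 ± 24.8 and 287 ± 14.8 CPM and Prl6a1 at 22.4 ± 9.28 and 42.9 ± 9.85 CPM (SD, n = 5 each).

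**Figure D2:**
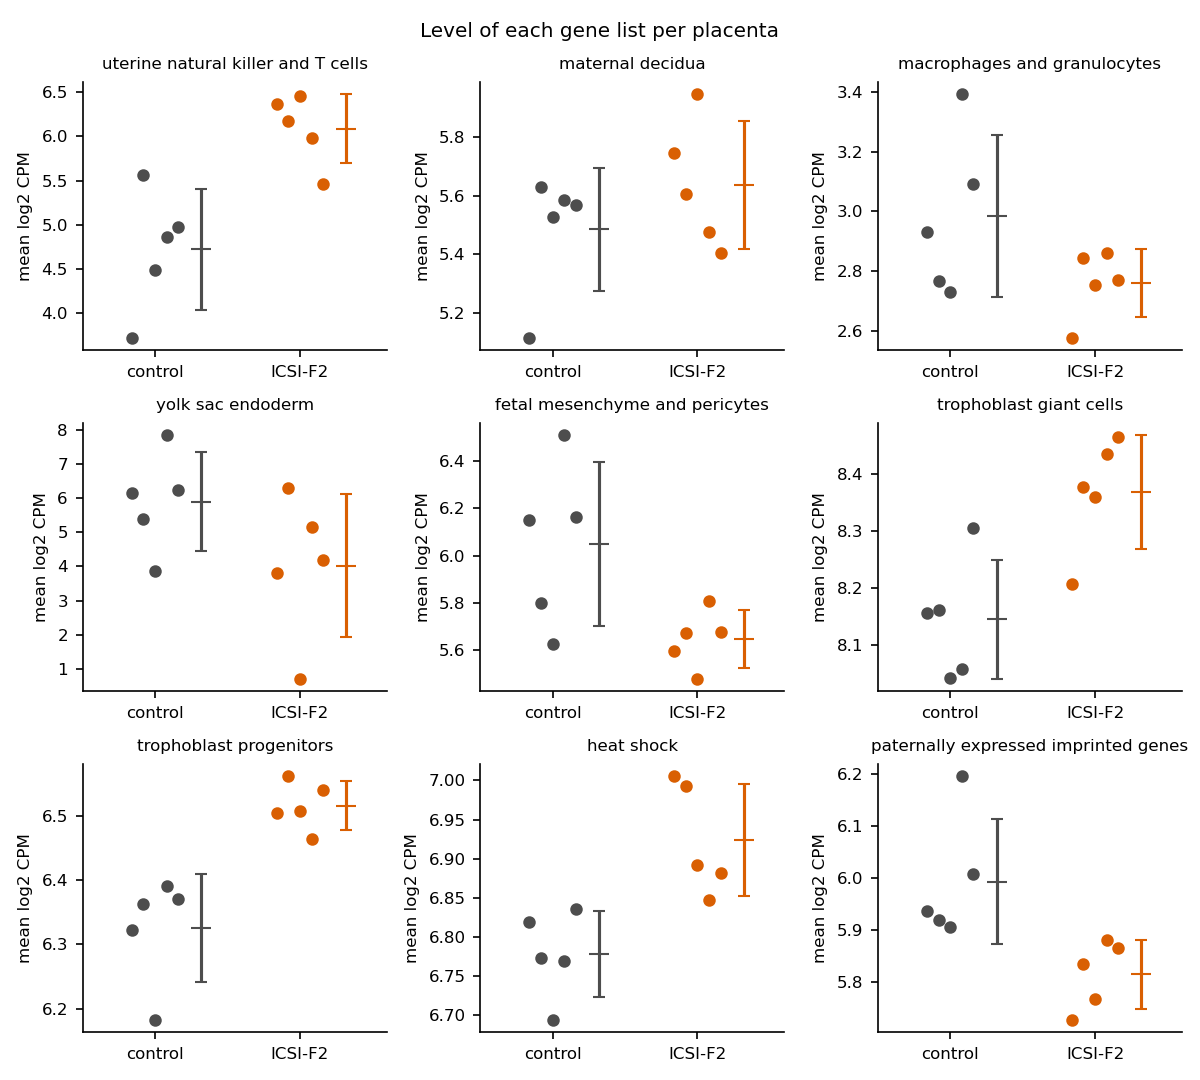
Level of 9 gene lists per placenta, as the mean log2 CPM over measured members (y axes differ and do not start at 0), in control (grey) and ICSI-F2 (orange), with a point per placenta and the mean and SD as dash and bar. The natural killer list averaged 4.72 in controls and 6.09 in ICSI-F2, while the yolk sac list ran from 3.87 to 7.86 in controls and from 0.695 to 6.29 in ICSI-F2.

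Most imprinted genes of both parental origins had lower values in ICSI-F2, and the difference between the 2 lists was not tested. Of 31 paternally expressed genes, 23 were lower in ICSI-F2, and the list fell by camera (adjusted p = 0.00159; adjusted p = 0.336 with an estimated correlation). All 5 ICSI-F2 levels lay below every control level, at 5.81 ± 0.0659 against 5.99 ± 0.120 log2 CPM (SD, n = 5 each, exact permutation p = 0.00794, 0.0952 adjusted). Within libraries with and without Y-linked reads the difference was −0.159 (exact permutation p = 0.12, 0.64 adjusted). Zdbf2, which controls postnatal growth in mice, averaged 78.1 ± 10.7 CPM in controls and 53.2 ± 10.7 in ICSI-F2, and Plagl1, a growth-regulating zinc finger gene, 288 ± 53.6 and 202 ± 37.5 (SD, n = 5 each). No member passed over the list alone. The difference of −0.18 became −0.0507 ± 0.0463 (SE) with the fetal mesenchyme level and −0.113 ± 0.0577 with the yolk sac level as a covariate. The maternally expressed list did not pass (24 of 34 lower, adjusted p = 0.0721), with Zim1 at 261 ± 18.1 and 189 ± 41 CPM and Ppp1r9a at 64.7 ± 4.34 and 53.2 ± 5.97 CPM (SD, n = 5 each). The 6 genes imprinted by maternal histone methylation had a median log2 fold change of −0.027 and a mean of 0.19, and did not pass (adjusted p = 0.993). They include Xist (log2 fold change 1.38), which raised that mean and was high in placentas without Y-linked reads.

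Among the imprinted genes named in advance, none passed the threshold by edgeR. Igf2, a growth factor gene, was 2715 ± 413 CPM in controls and 2443 ± 250 in ICSI-F2, with an adjusted p of 0.556. H19 was 6242 ± 635 and 6450 ± 336 CPM, Cdkn1c 799 ± 107 and 838 ± 81.1 CPM, and Peg10, a retrotransposon-derived gene needed for the placenta, 9690 ± 691 and 9738 ± 580 CPM (SD, n = 5 each). The direction of these 3 differences turned under several settings. Phlda2, a maternally expressed restrainer of placental growth, was 21 ± 8.46 and 35.8 ± 16.9 CPM (adjusted p = 0.356). Peg3 was 2940 ± 137 and 2636 ± 229 CPM (adjusted p = 0.372), and Rtl1 27.6 ± 4.10 and 25.0 ± 3.29 CPM (SD, n = 5 each). Sfmbt2 had a log2 fold change of 0.027 ± 0.0625, Slc38a4 of −0.17 ± 0.114, Jade1 of 0.13 ± 0.0684 and the spongiotrophoblast hormone gene Prl8a9 of −0.28 ± 0.177 (SE). Synb held 4 to 13 counts per library and was not tested. The DNA methylation machinery list did not pass (11 of 17 higher, median log2 fold change 0.030, mean −0.0067, adjusted p = 0.776), with Zfp57 at 11.8 ± 3.31 and 8.71 ± 1.92 CPM and Dnmt3b at 14.2 ± 1.65 and 16.1 ± 0.857 CPM (SD, n = 5 each). Germline genes silenced by DNA methylation did not pass either (12 of 15 lower, adjusted p = 0.0599). Of these, Syce1 was 0.976 ± 0.323 and 0.340 ± 0.258 CPM and Tex19.1 55.4 ± 7.96 and 66.8 ± 5.22 CPM (SD, n = 5 each).

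The heat shock list passed camera upwards, with 14 of 16 members higher, 3 passing over the list alone and an adjusted p of 0.000781 by camera (adjusted p = 0.336 with an estimated correlation). All 5 ICSI-F2 levels lay above every control level (6.92 ± 0.0709 against 6.78 ± 0.0551 log2 CPM, SD, n = 5 each, exact permutation p = 0.00794, 0.0952 adjusted). Hspb8, a small chaperone, was 89.3 ± 15.9 CPM in controls and 126 ± 15.1 in ICSI-F2, and its partner Bag3 111 ± 4.69 and 126 ± 5.10 (SD, n = 5 each). With the Y-linked list as a covariate the call ended (adjusted p = 0.0644), and within libraries with and without Y-linked reads the level difference was 0.0953 (exact permutation p = 0.12, 0.64 adjusted). The list of nuclear genes of the mitochondrial respiratory chain passed camera upwards by a small amount, with 29 of 33 members higher, none passing over the list alone, a mean log2 fold change of 0.11 and an adjusted p of 7.64e-06 by camera (adjusted p = 0.413 with an estimated correlation). Its exact permutation p was 0.0952 after adjustment, and 0.16 (0.64 adjusted) within libraries with and without Y-linked reads. With the Y-linked list as a covariate its level difference moved from 0.11 to 0.070. Cox4i1 was 120 ± 2.0 and 134 ± 7.62 CPM and Atp5j 42.8 ± 1.51 and 48.8 ± 3.37 CPM (SD, n = 5 each). The genes of the mitochondrial genome did not pass (5 of 11 higher, median log2 fold change −0.056, mean 0.058, adjusted p = 0.776).

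Genes of the list unfolded protein and integrated stress response were lower, with 21 of 25 down and 2 passing over the list alone (adjusted p = 0.0106 by camera; adjusted p = 0.607 with an estimated correlation). These 2 were Trib3, a pseudokinase target of the ATF4 pathway, at 15.6 ± 6.37 and 7.30 ± 1.39 CPM, and Sesn2, a stress-induced inhibitor of growth signalling, at 60.5 ± 7.39 and 48.4 ± 2.71 CPM (SD, n = 5 each). The mean difference was −0.14 on the log2 scale and did not exceed the spread of the samples (exact permutation p = 0.206, 0.351 adjusted). With the Y-linked list as a covariate it was −0.0061 (adjusted p = 0.743 by camera). The adjusted p was 0.217 with the code number, 0.13 without ICSI-F2 replicate 3, 0.0517 without control replicate 2 and 0.0519 without control replicate 4. Nutrient transport genes were lower, with 24 of 28 down and none passing over the list alone (adjusted p = 0.00112 by camera; adjusted p = 0.336 with an estimated correlation). Slc3a2, the heavy chain of amino acid transporters, was 258 ± 21.6 and 217 ± 21.6 CPM, and Trpv6, a calcium channel, 5.31 ± 3.54 and 2.28 ± 1.17 CPM (SD, n = 5 each). With the yolk sac list as a covariate the nutrient difference moved from −0.27 to −0.099. Growth factor signalling genes were lower (20 of 26, none over the list alone, adjusted p = 0.026 by camera; adjusted p = 0.414 with an estimated correlation), with Igf1 at 6.41 ± 2.44 and 3.22 ± 1.16 CPM and Igf2r at 688 ± 32.7 and 604 ± 39.9 CPM (SD, n = 5 each). The level difference of the list growth factor signalling was −0.20, and −0.16 with the Y-linked list as a covariate (adjusted p = 0.104) and −0.12 with the yolk sac list (0.0714), which ended the call. Within libraries with and without Y-linked reads it was −0.17 (exact permutation p = 0.16, 0.64 adjusted), so most of the difference stayed. The lost call is therefore no evidence for fetal sex as its source. With 1 control without Y-linked reads and 1 ICSI-F2 placenta with them, fetal sex cannot be excluded either. The call also ended without control replicate 4 (0.0675), control replicate 5 (0.0733) or ICSI-F2 replicate 2 (0.0632).

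Markers of other tissue parts varied between placentas. Yolk sac endoderm genes, from a membrane next to the placenta, were lower in all 18 measured members (mean log2 fold change −1.55, adjusted p = 6.04e-06 by camera; adjusted p = 0.45 with an estimated correlation). Their level was 5.90 ± 1.45 log2 CPM in controls and 4.03 ± 2.09 in ICSI-F2, which did not exceed the spread of the samples (SD, n = 5 each, exact permutation p = 0.151), and Alb went from 113 ± 160 to 18.3 ± 19.5 CPM. Without ICSI-F2 replicate 3 the difference of −1.87 was −1.05, and without both that placenta and control replicate 4, chosen after the values were seen, it was −0.55. Fetal mesenchyme and pericyte genes were lower in 11 of 15, with 5 lower and 1 higher over the list alone (adjusted p = 0.0417 by camera; adjusted p = 0.439 with an estimated correlation). Postn, a matrix protein of fibroblasts, averaged 103 ± 46.2 and 46.1 ± 9.59 CPM, while the pericyte gene Rgs5 averaged 277 ± 41.7 and 363 ± 17.7 CPM (SD, n = 5 each). Extracellular matrix genes were lower in 17 of 28, with 8 lower over the list alone (adjusted p = 0.045 by camera; adjusted p = 0.533 with an estimated correlation), including Eln, elastin, at 4.57 ± 3.56 and 1.05 ± 0.314 CPM and Col6a2 at 17.0 ± 9.27 and 6.34 ± 1.17 CPM (SD, n = 5 each). The level differences of the list fetal mesenchyme and pericytes and the list extracellular matrix were −0.40 and −0.31. With the Y-linked list as a covariate they stayed at −0.38 and −0.30 though both calls ended (adjusted p = 0.109 and 0.135). Within libraries with and without Y-linked reads they were −0.386 and −0.307 (exact permutation p = 0.2 and 0.24, 0.655 adjusted for each). These lost calls are therefore no evidence for fetal sex as a source, and they do not exclude it either. With the yolk sac list the level differences moved to −0.20 and −0.17 and both calls ended (0.244 and 0.295). Both calls also ended without control replicate 4 (0.0745 and 0.149), control replicate 5 (0.12 and 0.126), ICSI-F2 replicate 2 (0.0674 and 0.094), ICSI-F2 replicate 3 (0.0933 and 0.0885) or ICSI-F2 replicate 5 (0.0533 and 0.0857), and the matrix call also without ICSI-F2 replicate 1 (0.0528). Fetal erythroid genes were higher in 10 of 13, none over the list alone (adjusted p = 0.00842 by camera; adjusted p = 0.45 with an estimated correlation), with Rhag at 0.705 ± 0.187 and 1.94 ± 1.20 CPM and the embryonic globin Hba-x at 46.5 ± 11.4 and 75.7 ± 23.9 CPM (SD, n = 5 each). The level difference of the erythroid list did not exceed the spread of the samples (exact permutation p = 0.143, 0.302 adjusted). Without ICSI-F2 replicate 2 the erythroid difference moved from 0.35 to 0.22, and with the yolk sac list as a covariate its call ended (0.0568).

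**Figure D3:**
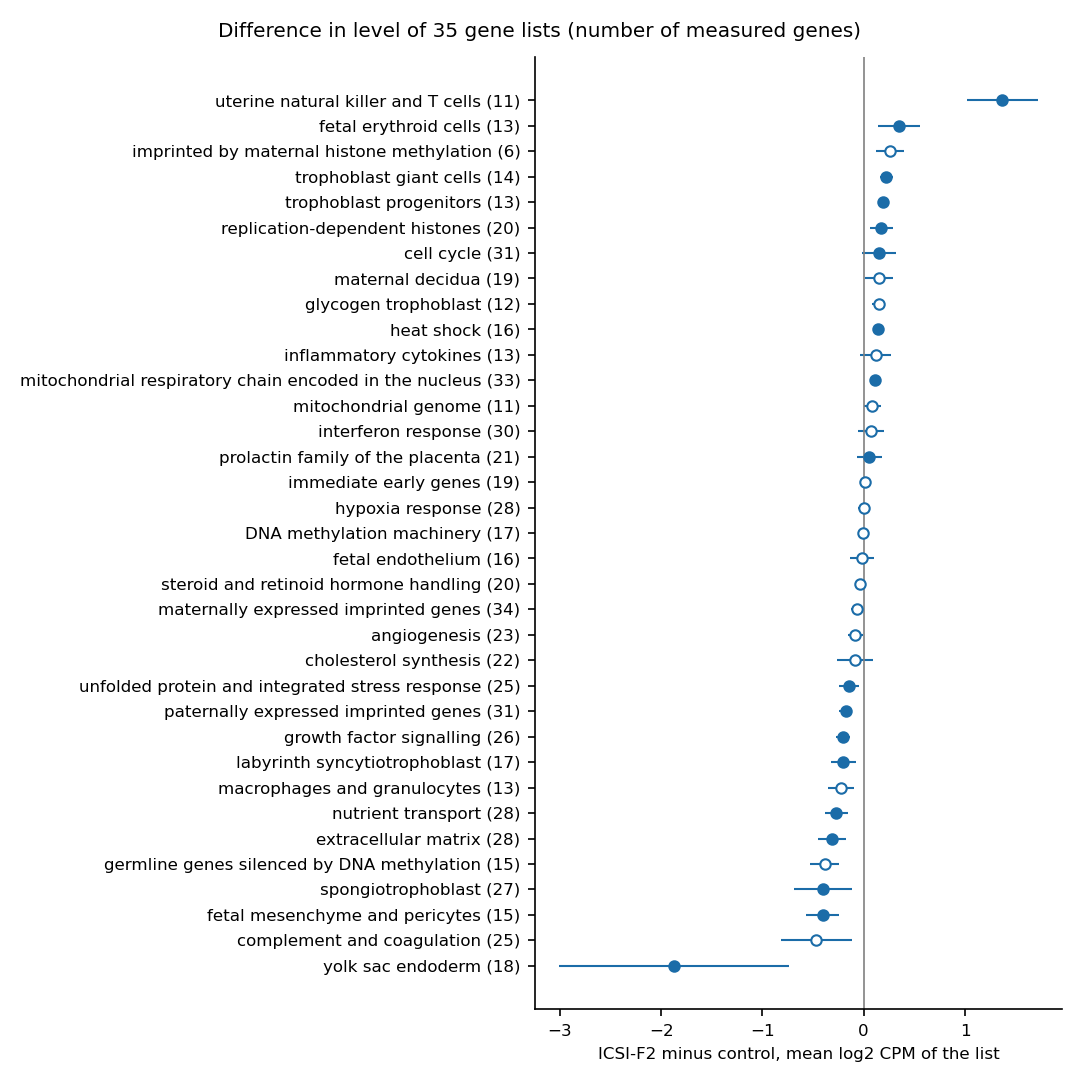
Difference in the mean log2 CPM of 35 gene lists, ICSI-F2 minus control (x axis), without the Y-linked list, with the number of measured genes in parentheses, and points with the SE of the difference, filled where camera with the preset correlation gave an adjusted p under 0.05. The natural killer list lies farthest up at 1.37, and the yolk sac list farthest down at −1.87 with the widest bar.

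The groups also differed in the share of placentas with Y-linked reads. The 4 Y-linked genes together held 3334 to 3854 counts in 4 control placentas and in 1 ICSI-F2 placenta, and 0 to 8 in the other placentas (Fisher's exact two-sided p = 0.206). Xist, the RNA that silences an X chromosome in female cells, was 2412 to 2870 CPM in the placentas without Y-linked reads and 264.7 to 395.2 CPM in those with them. The log2 fold change of Xist between the groups was 1.38 ± 0.751 (SE) and turned to −0.28 with the Y-linked list as a covariate. The Y-linked list passed camera downwards (all 4 members lower, none over the list alone, adjusted p = 0.00343; adjusted p = 0.421 with an estimated correlation), with Kdm5d at 24.5 ± 13.7 and 5.42 ± 12.1 CPM and Uty at 32.9 ± 18.5 and 8.15 ± 18.2 CPM (SD, n = 5 each).

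**Figure D4:**
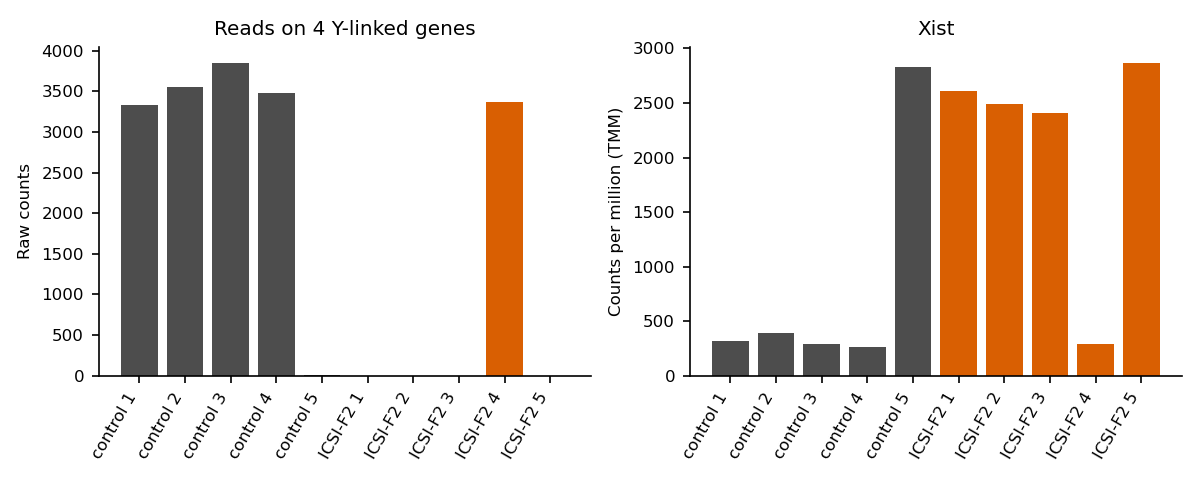
Raw counts on 4 Y-linked genes (left) and Xist in TMM-scaled CPM (right) in each of the 5 control (grey) and 5 ICSI-F2 (orange) placentas. Y-linked counts are 3334 to 3854 in 5 placentas, 4 of them controls, and at most 8 in the others, where Xist is 2412 to 2870 CPM.

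Proliferation lists passed camera upwards in ICSI-F2, the group with fewer placentas carrying Y-linked reads, but their levels did not differ beyond the spread of the samples (exact permutation p = 0.389 for cell cycle and 0.167 for histones, 0.538 and 0.316 adjusted). Of 31 cell cycle genes, 29 were higher (adjusted p = 0.0044 by camera; adjusted p = 0.701 with an estimated correlation), with Cdkn1a, a cell cycle inhibitor, at 28.2 ± 3.90 and 35.3 ± 3.13 CPM and Pcna, the replication clamp, at 43.4 ± 5.43 and 52.2 ± 4.76 CPM (SD, n = 5 each). All 20 replication-dependent histone genes were higher (adjusted p = 0.00295 by camera; adjusted p = 0.533 with an estimated correlation), with Hist1h3a at 6.94 ± 1.61 and 9.57 ± 1.77 CPM and Hist1h1a at 51.7 ± 12.9 and 69.1 ± 15.9 CPM (SD, n = 5 each). No member of either list passed over the list alone, and histone genes have near-identical copies that may share reads. With the Y-linked list as a covariate the cell cycle difference turned from 0.15 to −0.049 (adjusted p = 0.359), and the histone difference moved from 0.17 to 0.017 (adjusted p = 0.787). With the code number as a covariate both calls ended (0.222 and 0.208). The cell cycle call also ended without control replicate 2 (0.211), ICSI-F2 replicate 2 (0.149) or ICSI-F2 replicate 3 (0.0943).

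In total 19 of the 36 lists passed camera with its preset correlation, 9 higher and 10 lower, and 0 passed with an estimated correlation (smallest adjusted p 0.336). Some lists share members, so these calls are not independent. For example, Prl2c3 is in the giant cell and prolactin lists, and Slc13a4 in the labyrinth and yolk sac lists. The exact permutation of list levels gave 10 lists at an unadjusted p under 0.05 and 0 after adjustment (smallest 0.0952). The directional test fry, which asks whether a list's genes move one way on balance, gave 0 lists with a smallest adjusted p of 0.0511, and its test for change in either direction gave 14 lists. The smallest directional p lay so near the threshold that entering the ICSI-F2 libraries first gave 5 lists at 0.0496.

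Placentas of the 2 groups varied to a similar degree. The root mean square distance of a placenta from its group mean over all tested genes was 0.330 ± 0.0476 log2 CPM in controls and 0.322 ± 0.0555 in ICSI-F2 (SD, n = 5 each). The difference in spread between samples within groups, ICSI-F2 against control, was −0.0080 and did not exceed the spread (exact two-sided permutation p = 0.81), and its sign turned without control replicate 4 (0.0221) or control replicate 3 (0.0123).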

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

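The tests of the median decidua level, fetal sex, code number and other immune cells for the natural killer genes, both tests of the yolk sac genes, and the test of fetal sex for the imprinted genes were chosen after the result was seen.

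A placenta stood apart from the rest of its group in 16 of 254 groups of values, where chance alone gives about 13. The values that follow are the gap to the nearest other placenta divided by the range of the group. Control replicate 5, the control without Y-linked reads, was low in Kdm5d (0.979), Uty (0.983) and the Y-linked list (0.96) and high in Xist (0.831). ICSI-F2 replicate 4, the ICSI-F2 placenta with Y-linked reads, was high in Kdm5d (1), Uty (1) and the Y-linked list (1) and low in Xist (0.925). It was also low in the list imprinted by maternal histone methylation (0.754), which includes Xist. Control replicate 5 was also high in Gcm1 (0.727) and low in Peg3 (0.891) and P4ha2 (0.711). Control replicate 1 was high in Ceacam9 (0.896) and low in the maternal decidua list (0.801). ICSI-F2 replicate 3 was low in Ogn (0.711) and P4ha2 (0.733).

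The uterine natural killer and T cell list was 1.37 log2 higher in ICSI-F2. With the mean of the decidua list without Gzme as a covariate (0.0713 higher in ICSI-F2) the difference was 1.2 ± 0.225 (SE). With the median level of that list per placenta as a covariate (0.31 higher) it was 1.01 ± 0.328. Members of the decidua list moved together only weakly (estimated correlation 0.22), so the list measures decidua imprecisely. The difference that stayed therefore cannot exclude more maternal decidua as the cause, in part or whole. The natural killer and T cell difference was 1.24 ± 0.463 with Y-linked reads and 1.34 ± 0.411 with the code number as a covariate. This argues only weakly against either as the whole cause, since few libraries separate them from the group. Only 1 control lacked Y-linked reads and 1 ICSI-F2 placenta had them, and ICSI-F2 replicate 1 alone had code number 37 in its group. The macrophage and granulocyte list differed by −0.222 ± 0.131, with 10 of 13 members lower. That argues only against a rise of these genes as a set alongside the natural killer list. The list mixes macrophage and granulocyte genes, so it cannot tell whether immune cells of other kinds rose. Its member S100a8 was higher, so a rise of some other immune cells stays open. A higher content of uterine natural killer or T cells in ICSI-F2 placentas may be put forward as a hypothesis, found and tested on the same data. A difference between dams, or in how much of the maternal side was dissected, was not tested, since the labels give neither.

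The yolk sac list was lower by a level difference of −1.87 ± 1.14 (SE) and uneven within groups. Within groups its members moved together, with a median correlation of 0.966 of a member with the others and a median slope of 1.14, which is consistent with different amounts of yolk sac tissue in the samples. Lower expression in ICSI-F2 placentas cannot be told apart from this, because the difference did not exceed the spread of the samples (exact permutation p = 0.151).

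Paternally expressed imprinted genes were lower by a level difference of −0.178. With Y-linked reads as a covariate the difference was −0.159 ± 0.0811 (SE), with the fetal mesenchyme level −0.0507 ± 0.0463, and with the yolk sac level −0.113 ± 0.0577. Each of these lies between 1 and 2 SE from 0, so unequal fetal sex, less fetal mesenchyme and less yolk sac tissue cannot be told apart from a difference tied to the ICSI-F2 group, which stays open and was not tested separately.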

How the results depend on the processing

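The alternatives with the yolk sac list or without both ends of its range, the 2 other sample orders of fry, and the code number with the Y-linked list for gene lists were chosen after seeing the data. The camera calls of the giant cell, natural killer, paternally expressed imprinted, nutrient transport, nuclear respiratory chain and yolk sac lists stayed past the threshold under every filter, normalization, covariate and left-out library tried, and ended with an estimated correlation and with fry in the planned order. Of the values of named genes with all libraries of a setting, 1880 kept direction and side of the threshold, 77 passed it and 40 reversed; with a library left out, 895 kept both, 5 passed and 10 reversed. For lists these were 384, 24 and 22, with 106 no longer past; with a library left out 299, 21 and 16, with 24 no longer past. A list used as a covariate got no value of its own under that setting. Where no cause is named, the cause was not tested. The smallest simulated change was recovered in 10% of genes by edgeR, so small changes are largely missed at this depth and number of placentas.

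The number of genes past the threshold, ICSI-F2 against control, was 0 and became 1 with no filter on low counts, 313 with the DESeq2 Wald test, 1 with limma voom, 1 with voom and sample weights, 10 with the code number as covariate, 1 in only code number 63, 4 in only code number 37, 31 with the library name style as covariate, 198 in only names with a "_" and 4 in only names without it. In both code number 37 and names with a "_" every control had Y-linked reads and no ICSI-F2 placenta had them, so group and fetal sex cannot be separated there. The 4 calls in code number 37 were all sex genes (Kdm5d, Uty, Ddx3y and Xist), and those in names with a "_" included the same genes and Eif2s3y. Leaving out each library gave 0 to 4. The number of gene lists past the threshold, ICSI-F2 against control, was 19 and became 12 with the Y-linked list as covariate, 0 with an estimated correlation, 0 with fry, 0 with fry in reverse order and 5 with fry and the ICSI-F2 samples first. The spread between samples within groups, ICSI-F2 against control, was 0.000526 with a mean of 50 counts per library, 0.00195 with counts summed per number and letter, and −0.0418 to 0.0221 leaving out each library.

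Some named genes reversed. With a mean of 50 counts per library the log2 fold change of Peg10 was −0.000603, and with voom and sample weights the log2 fold change of Tpbpa was −0.0516. With the code number as covariate the log2 fold change of H19 was −0.0298, the log2 fold change of Cdkn1c −0.0205 and Peg10 −0.0373. In only code number 63 H19 was −0.0605, the log2 fold change of Slc38a4 0.0339, Cdkn1c −0.00762 and Peg10 −0.00691. In only code number 37 the log2 fold change of Flt4 was −0.00505, Tpbpa −0.0745, Cdkn1c −0.0303 and Peg10 −0.0785. In names with a "_" Tpbpa was −0.314, the log2 fold change of Sfmbt2 −0.0153 and Peg10 −0.00513. In names without it the log2 fold change of Hist1h1a was −0.0927, the log2 fold change of Uty 0.06, H19 −0.0722, the log2 fold change of Peg3 0.00984, the log2 fold change of Prl8a9 0.246, the log2 fold change of Phlda2 −0.177 and Slc38a4 0.216. With the Y-linked list as covariate the log2 fold change of Xist was −0.276, H19 −0.000764, Slc38a4 0.0493, Cdkn1c −0.0523, Sfmbt2 −0.011 and Peg10 −0.0393. With the code number and Y-linked list Xist was −0.27, Hist1h1a −0.0392, Uty 0.0507, H19 −0.0514, Slc38a4 0.0833, Cdkn1c −0.105 and Peg10 −0.0665. Sfmbt2 was −0.0147 with 1 surrogate variable, −0.00871 with the yolk sac list and −0.00941 without both ends of its range, where Peg10 was −0.00137. Leaving out each library gave −0.103 to 0.113 for Tpbpa, −0.015 to 0.0579 for Sfmbt2 and −0.0172 to 0.0443 for Peg10.

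These level differences of lists reversed. With no filter the list DNA methylation machinery was 0.00148. With a mean of 50 counts the list hypoxia response was −0.0104, the list steroid and retinoid hormone handling 0.00236 and the list mitochondrial genome −0.0372. With the Y-linked list as covariate the list spongiotrophoblast was 0.0028, the list imprinted by maternal histone methylation −0.0408 and the list cell cycle −0.049. With the code number added these were 0.0421, −0.0231 and −0.0899, and the list unfolded protein and integrated stress response was 0.00793, mitochondrial genome −0.0129 and the list replication-dependent histones −0.0298. With the yolk sac list DNA methylation machinery was 0.00686, the list interferon response −0.0468, the list complement and coagulation 0.0891, the list cholesterol synthesis 0.116 and the list immediate early genes −0.0313. Without both ends of the yolk sac range cholesterol synthesis was 0.0444 and immediate early genes −0.00749, and with the decidua list hypoxia response was −0.00749 and immediate early genes −0.0145. Leaving out each library gave −0.0128 to 0.114 for the list prolactin family of the placenta, −0.082 to 0.0600 for the list fetal endothelium, −0.0313 to 0.00642 for DNA methylation machinery, −0.0335 to 0.0388 for hypoxia response and −0.179 to 0.0161 for cholesterol synthesis.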

Other observations

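None of the vascular and clotting lists passed, and of their members Cdh5, F3, Cd55 and Procr passed adjusted over the list alone. Cdh5, the adhesion protein of endothelial junctions, averaged 1137 ± 56.4 CPM in controls and 1373 ± 41.8 in ICSI-F2 and was higher in 5 of 5 placentas (SD, n = 5 each), while Plvap, a protein of endothelial pores, averaged 57.6 ± 6.87 and 46.8 ± 7.99 CPM. The fetal endothelium list had 8 of 16 members higher (median log2 fold change −0.000285, mean −0.0057, test upwards, adjusted p = 0.993 by limma's camera), and Cdh5 alone passed adjusted over the list alone. Angiogenesis genes had 9 of 23 higher (adjusted p = 0.759), with Angpt2 at 51.7 ± 8.70 and 71.7 ± 13.2 CPM. Hypoxia genes had 11 of 28 higher (median −0.0393, mean −0.00322, test upwards, adjusted p = 0.993), with Pfkfb4 at 14.3 ± 2.30 and 18.2 ± 2.37 CPM. Complement and coagulation genes had 10 of 25 higher (adjusted p = 0.901), and 3 passed adjusted over the list alone: F3, which encodes the tissue factor that starts coagulation, was 45.8 ± 8.44 CPM in controls and 30.6 ± 3.87 in ICSI-F2, Cd55, a brake on complement, was 44.4 ± 9.08 and 69.4 ± 14.5 CPM, and Procr was higher.

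None of the hormone, inflammation and immediate early lists passed, and Icam1 was their only member to pass adjusted over the list alone. The steroid and retinoid list had 10 of 20 higher (adjusted p = 0.901 by limma's camera), with Star, which carries cholesterol into mitochondria, at 55.9 ± 12.9 and 89.2 ± 19.4 CPM and Cyp11a1, the enzyme that begins steroid synthesis, at 123 ± 28.8 and 185 ± 42.4 CPM (SD, n = 5 each). Cholesterol synthesis genes had 13 of 22 lower (adjusted p = 0.464), with Stard4 at 92.6 ± 18.5 and 71.9 ± 11.3 CPM. Inflammatory cytokine genes had 10 of 13 higher (adjusted p = 0.0531), with Icam1 at 36.5 ± 1.37 and 42.4 ± 1.22 CPM. Interferon response genes had 19 of 30 higher (adjusted p = 0.442) and immediate early genes 11 of 19 (adjusted p = 0.526), with Oasl1 at 2.38 ± 0.842 and 3.33 ± 0.889 CPM and Ier3 at 32.1 ± 4.23 and 41.3 ± 4.93 CPM.

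Of 100 drawn splits of the 10 libraries, the real one included, 7 gave as many genes at an unadjusted p under 0.05 as the real split (2049, highest other 2590), so chance could not be excluded. For DESeq2's Wald test 7 of 100 gave as many calls (313, highest other 754), and chance could not be excluded there either; 42 other splits gave at least 1 call. For gene lists 2 of 100 gave as many (19, highest other 21), a share under 0.05, which excludes chance only if the libraries are exchangeable, and only for camera with a preset correlation. Libraries that share a code number and letter always lay in the same group, with a consensus correlation of 0.282, and the number of gene lists past the threshold, ICSI-F2 against control, was 12 with the Y-linked list as covariate. The other splits had a median of 9 lists, and 0 lists passed with an estimated correlation or adjusted permutation. By edgeR 4 other splits had genes past the threshold, 2 of them with a single gene and the highest with 146 against 0 in the real split. A count that high points to a structure of the samples, and what it follows was not tested.

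The genes with the smallest p may follow the cell content of the samples. Within groups, the 100 such genes that were higher in ICSI-F2 had a median correlation of 0.319 with the natural killer list level, above the highest of 10000 random lists (0.135). The 100 that were lower had a median of 0.245 with the fetal mesenchyme level, barely above the highest random list (0.243). Both are hypotheses, and correlated genes are not independent.

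Genes outside the sex chromosomes may follow fetal sex. The split by Y-linked reads gave 15 genes past the threshold by edgeR, with 1781 at an unadjusted p under 0.05. Of the 15, 6 were not annotated to the X or Y chromosome, a count that may include genes without a known position. Since 4 of 5 controls and 1 of 5 ICSI-F2 placentas had Y-linked reads, group and fetal sex overlap.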
